A study of Homo sapiens with 45 samples.

How the data were processed

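The libraries were made from polyadenylated RNA, per the labels, with RNA from a column kit and an mRNA library kit. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.20.0 and quantified with RSEM (version not given in the sources used here) on GRCh38. The aligner, the annotation release and the strand used for counting are not given in the sources used here, so levels of genes that overlap others, on the same or the opposite strand, are uncertain. POU5F1 also has pseudogenes that can share reads with it.

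The deposited expected counts are RSEM estimates that the authors made by sharing ambiguous reads among genes. Of the values per gene and library, zeros included, 92.5% are whole numbers. They were rounded to whole numbers here and were not otherwise changed. The deposited TPM values were scaled by the authors with RSEM for gene length and library total, and each library sums to between 999999 and 1000001. They were used here only as an alternative.

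The tables hold 58233 genes, of which 57895 have an identifier in GENCODE release 29, and the other 338 hold 0.0276% of the counts. Gene types and positions come from that release. The mouse part of the series was not analysed here. The choices and lists described here were made before the data were examined, except where the text says otherwise.

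Counts were fitted with edgeR 4.0.16 in R 4.3.3 (TMM factors, default filter on low counts by day, robust quasi-likelihood fit, quasi-likelihood F test), with day as a factor and all 45 libraries in 1 fit with 30 residual degrees of freedom. The filter left 19437 genes, and the TMM factors lay between 0.9247 and 1.061. The dispersion that entered the fit, as a biological coefficient of variation, was 6.09% (median). It leaves out the gene-specific quasi-likelihood dispersions, so it is not the full spread between replicates. P-values were adjusted with the Benjamini-Hochberg method over all genes tested in a comparison, and a gene was called at an adjusted p under 0.05. With 3 libraries against 3, an exact permutation test cannot go below a p of 0.1, so the tests rest on the spread shared over all days and genes. Principal components were taken from log2 CPM (prior count 2) of the 1000 most variable genes tested.

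For genes with no counts in the 3 libraries of a day, the fold is a lower bound against a floor of 3 counts over the group. For 1 to 3 counts, the ratio is given with its 95% counting interval in place of the fitted fold.

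Genes were named by a rule. In each stage these are the 8 called protein-coding genes with the highest and the 8 with the lowest log2 change, if their mean was at least 10 CPM on the higher day and the libraries of both days did not overlap. Chance gives no overlap for 10% of genes with 3 libraries against 3. From each list up to 4 called members with the largest change were named, with a panel of 46 genes. Other members are named where they moved against the rest of their list, or in small groups, and were chosen after their values were seen. Results for some genes that the rule names are not reported here.

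There were 30 gene lists, tested with camera in limma 3.58.1 on log2 CPM with a preset correlation of 0.01, adjusted over all lists and the 4 stages together. Each test was repeated with the correlation estimated. The lists cover pluripotency, neuromesodermal progenitors, mesoderm, RA response, Hedgehog targets, HOX groups 1 to 4, 5 to 8 and 9 to 13, neural progenitors, ventral progenitors, neurogenic genes with Notch ligands, Notch targets, somatic and visceral motor neurons, pan-neuronal genes, floor plate with p3, other interneurons, neural crest with roof plate, gliogenic and oligodendrocyte genes, endoderm with endothelium, non-neural ectoderm, the cell cycle, immediate early genes, hypoxia with glycolysis, p53 targets, cholesterol synthesis, the proteasome, and early and late progenitor age. Some genes, not all of them named here, are in more than 1 list: LIN28A (pluripotency and early age), CYP26A1 (neuromesodermal and RA), HOXB1 (RA and HOX 1 to 4), HES5 (neural progenitor and Notch), EVX1 (neuromesodermal and interneuron), SOX10 (crest and oligodendrocyte), NFIA and NFIB (gliogenic and late age), and NKX2-2, NKX2-8 and FOXA2 (Hedgehog and floor plate, with NKX2-2 also in ventral progenitors).

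The alternatives were DESeq2 1.42.0, its size factors within edgeR, no filter on low counts (37282 genes), a change of at least 2-fold, a term for the replicate number, a fit of each pair of days alone, each replicate number and each library of a stage left out, and limma on log2(TPM + 1) for 18075 genes with a TPM of at least 1 in 3 libraries.

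The steps were tested on simulated data. Counts were simulated for the 19437 genes tested, from the comparison of day 15 with day 8, and 19235 of them passed the filter again. Apart from a list, 200 genes were changed, all drawn from genes above a minimum mean CPM on day 8, so none lay near the floor of few counts. In these data edgeR called 54% of 50 genes changed 1.25-fold, 76% of those changed 1.5-fold, 94% of those changed 2-fold and 98% of those changed 4-fold. It called 19 of the 19206 genes simulated as unchanged (0.099%), those below the filter included, and camera called 0 of 29 unchanged lists. Genes were drawn independently of each other, so this does not show how often camera calls unchanged lists of correlated genes. In the real comparison of these days 51.7% of genes were called, a far larger share than was changed here. The shares recovered and falsely called here therefore need not hold for the real data.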

Results

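Messenger RNA was measured over time in cells derived from H9, an established human embryonic stem cell line. The cells had first been grown as neuromesodermal progenitors, the tail bud cells that give rise to spinal cord and paraxial mesoderm. On day 0 they were replated in retinoic acid (RA, 100 nM), which patterns the hindbrain and spinal cord, and SAG (500 nM), an agonist of Smoothened that activates the Hedgehog pathway. The labels give 45 libraries from 15 days, days 0 to 15 without day 3, with 3 libraries per day. Day 0 is labelled as the control, so time, treatment and replating changed together after it. The library totals ran from 22835855 counts in day 4 replicate 2 to 39066300 in day 15 replicate 3, and 23042 to 25099 genes had counts. Mitochondrial genes held 2.241% to 3.208% of the counts on day 0 and 3.653% to 5.287% on day 1. They held 1.795% to 2.348% on day 8 and 4.081% to 4.352% on day 15. Whether this share reflects cell or RNA quality was not tested. The labels call the replicates only bioreps, so the p-values here measure only the spread between these samples. Levels are read counts scaled to the library size (CPM), given as mean ± SD with n = 3, and log2 changes are given ± SE. Intervals and lower bounds cover counting error only. For gene lists, the number of members that changed comes from p-values adjusted over all genes tested; where no second number is given, the number adjusted over the list alone was the same.

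The libraries separated by day. In the 1000 most variable genes the first principal component held 63.8% of the variance and the second 17.1%. With the mean of day 0 placed at 0% and that of day 15 at 100%, the first component put day 1 at 6.4% ± 0.42, day 4 at 40.2% ± 0.83, day 8 at 79.5% ± 0.2 and day 14 at 99.2% ± 0.3. These positions moved with the genes used, with day 1 at 7.8% in the 500 most variable genes and at 4.3% in the 5000 most variable, and day 4 at 40.4% and 38%. Days 0 and 1 lay close on the first component but far apart on the second, at -63.5 ± 1.28 and -8.5 ± 0.56. Of 19437 genes tested, 17930 (92.2%) differed between some of the 15 days (edgeR quasi-likelihood F test, Benjamini-Hochberg adjusted p under 0.05). The time course was then read in 4 stages, days 0 to 1, 1 to 4, 4 to 8 and 8 to 15, each as the later day against the earlier one.

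**Figure D1:**
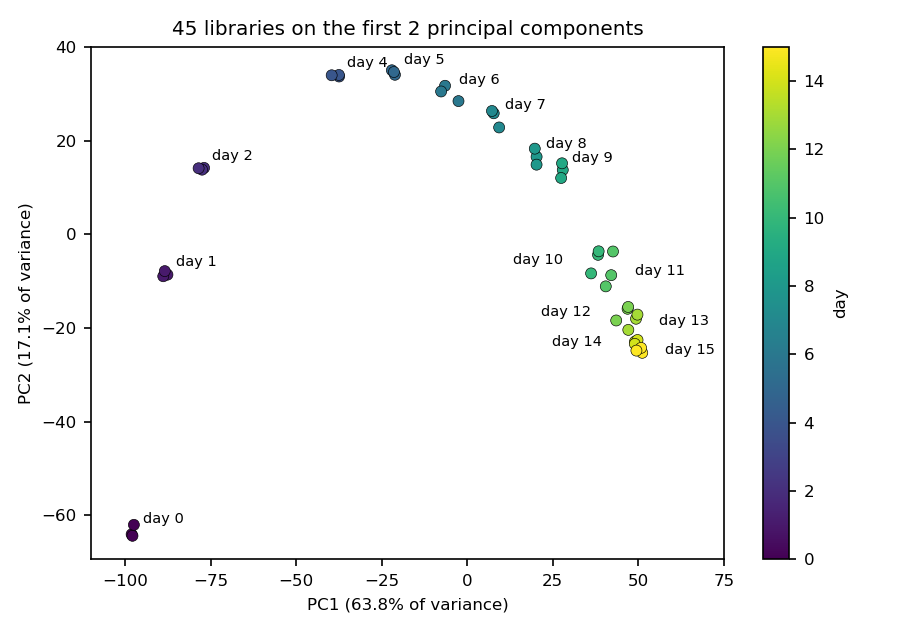
Principal components of log2 CPM in the 1000 most variable genes, with 1 point per library coloured by day (first component on the horizontal axis, second on the vertical, both in units of log2 CPM). The days run in order along the first component (63.8% of the variance), and day 0 stands apart on the second (17.1%).

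**Figure D2:**
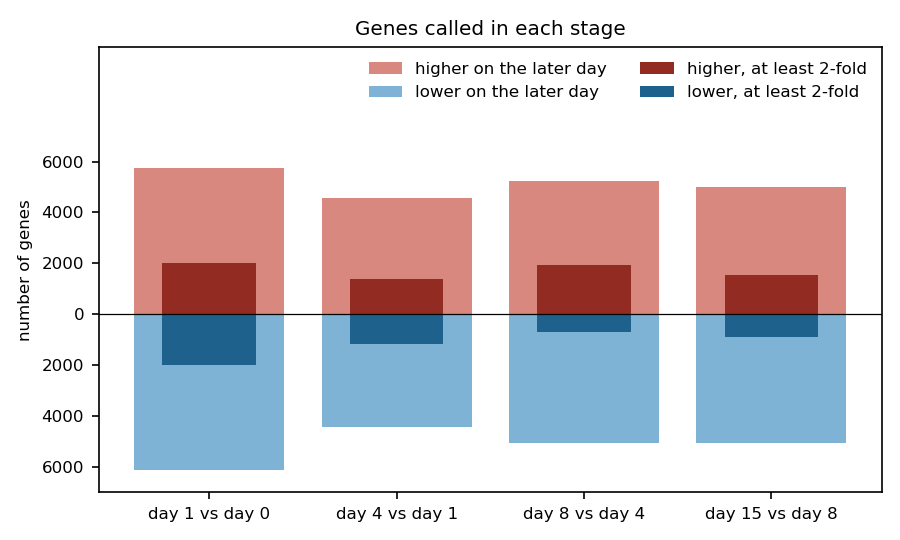
Number of genes (vertical axis) higher or lower on the later day of each stage at an adjusted p under 0.05, upward and downward bars, with the part that changed at least 2-fold in dark. The first stage has the most calls, 5743 up and 6137 down of 19437 genes tested.

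The comparison of day 1 with day 0 addresses the first day in RA and SAG, which also included dissociation and replating. Within that day PAX6, a transcription factor of neural progenitors (ENSG00000007372, chromosome 11, 31784779 to 31818062 in GRCh38, overlapping ELP4), went from 0.215 ± 0.094 to 402 ± 5.5 CPM, a log2 change of 10.85 ± 0.12 (adjusted p = 7.4e-42). HES5, a Notch-responsive repressor that keeps neural progenitors from differentiating, had 1 count over the day 0 libraries and 131 ± 5 CPM on day 1, a ratio of 12797 (95% counting interval 2296 to 505513). The tail bud factor NKX1-2 (ENSG00000229544, chromosome 10, 124445239 to 124450184) fell from 978 ± 66 to 25.8 ± 1 CPM, and IL17RD, a feedback inhibitor of FGF signalling, fell from 719 ± 52 to 7.4 ± 0.063 CPM. In all, 5743 genes were higher and 6137 lower on day 1, and 1995 and 2003 of these changed at least 2-fold.

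The other genes with the largest rises were a mixed group. FEZF2, a forebrain transcription factor, was not counted on day 0 and stood at 28.2 ± 1.7 CPM on day 1, at least 919.9-fold higher. The proneural factor NEUROG1 was at least 359-fold higher and the myelin-associated gene MOBP at least 397-fold higher. CLDN2, a tight junction gene that overlaps MORC4 and RIPPLY1, was at least 740.4-fold higher. Among the largest falls were the FGF-induced factors ETV5 (146 ± 6.3 to 2.26 ± 0.29 CPM) and ETV4 (107 ± 4.9 to 1.81 ± 0.31 CPM), which overlap DGKG and DHX8. The mid-hindbrain and kidney factor PAX2 fell from 28 ± 9.2 to 0.54 ± 0.16 CPM. LRAT, which esterifies retinol, fell from 16.4 ± 3.8 to 0.308 ± 0.11 CPM, and LY6G6D, which overlaps a readthrough gene, had a log2 change of -6.03 ± 0.3.

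Genes of the starting cells were lower on day 1. Of 11 neuromesodermal progenitor genes tested, 9 fell and 2 rose (camera adjusted p = 9.7e-05, and 0.043 with an estimated correlation). EVX1 fell from 14.9 ± 10 to 0.0919 ± 0.045 CPM, FGF17 from 216 ± 73 to 2.48 ± 0.31 CPM and WNT8A from 26.3 ± 5.8 to 0.564 ± 0.1 CPM. TBXT, the tail bud factor also called Brachyury, fell from 23.7 ± 9.7 to 0.964 ± 0.29 CPM. The 2 that rose were WNT3A, a Wnt ligand, and CYP26A1, an RA-degrading enzyme that RA itself induces. Of 7 pluripotency genes, 6 fell and PRDM14 did not pass (camera adjusted p = 0.00014, and 0.0076 with an estimated correlation). LIN28A, an RNA-binding protein of early embryonic cells, fell from 2964 ± 165 to 576 ± 6.4 CPM, and POU5F1 (OCT4), which overlaps TCF19, fell from 73.4 ± 5.5 to 10.2 ± 0.69 CPM.

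All 12 neural progenitor genes rose (camera adjusted p = 1.3e-11, and 0.0031 with an estimated correlation). SOX1 rose from 2.35 ± 0.67 to 129 ± 3.4 CPM and SOX21 from 1.09 ± 0.76 to 66.5 ± 1.7 CPM. Of 13 neurogenic and Notch ligand genes, 12 rose, and HES6 did not pass (camera adjusted p = 1.3e-11, and 0.035 with an estimated correlation). GADD45G, a stress and neurogenesis gene, rose from 0.0818 ± 0.036 to 21.4 ± 0.65 CPM. Of 7 Notch target genes, 6 rose over all genes tested and 7 when adjusted over the list alone, among them HES4 (0.643 ± 0.007 to 24.6 ± 1 CPM). Their camera call (adjusted p = 0.00022) was lost at an adjusted p = 0.11 with an estimated correlation.

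RA-responsive genes went both ways. Of 10, 6 rose and 3 fell, and camera did not call the list (adjusted p = 0.066). RARB, an RA receptor gene that RA induces, rose from 0.173 ± 0.034 to 110.1 ± 2.5 CPM, a log2 change of 9.28 ± 0.18 (adjusted p = 1.7e-33). CYP26A1 rose from 0.55 ± 0.8 to 12 ± 0.11 CPM. The retinol uptake receptor STRA6 fell from 161 ± 17 to 14.2 ± 0.18 CPM, TGM2 from 0.683 ± 0.063 to 0.0476 ± 0.017 CPM, and the third that fell was HOXB1. Of 7 Hedgehog target genes, 6 rose and FOXA2 fell (camera adjusted p = 0.0079, lost at an adjusted p = 0.22 with an estimated correlation). HHIP, a Hedgehog-binding feedback inhibitor, stood at 43.1 ± 1.1 CPM on day 1, a ratio of 4235 to day 0 (counting interval 759.7 to 167327), and GLI1 rose from 21 ± 1.2 to 77.9 ± 3.7 CPM. NKX2-2 and NKX2-8 rose to 0.117 ± 0.043 and 0.157 ± 0.021 CPM, and their calls, like that of FOXA2 (1.28 ± 0.3 to 0.271 ± 0.058 CPM), were lost without replicate 1 and without replicate 2. Those of NKX2-2 and NKX2-8 were also lost with TPM (0.48 and 0.23), and that of NKX2-8 without replicate 3 (0.083) and without the filter on low counts (0.11). RARB, STRA6, TGM2 and GLI1 overlap other protein-coding genes (TOP2B, CCDC33, RPRD1B and ARHGAP9).

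HOX genes, which mark position along the body axis, changed in both directions. HOX groups 9 to 13 had 4 of 16 genes tested and 3 fell, with HOXB9 going from 846 ± 47 to 134 ± 0.46 CPM. That list's camera call (adjusted p = 0.041) was lost with an estimated correlation (adjusted p = 0.2), without replicate 2 (0.13), without replicate 3 (0.051) and with TPM (0.055). In groups 5 to 8, 3 of 11 rose and 6 fell, and HOXC8 fell from 20.3 ± 5.7 to 0.406 ± 0.022 CPM (camera adjusted p = 0.23). In groups 1 to 4, 5 of 12 rose and 6 fell (camera adjusted p = 0.66), and HOXD4 rose from 7.44 ± 1.3 to 46.6 ± 1.4 CPM while HOXC4 fell from 65 ± 14 to 10.3 ± 0.94 CPM. In the annotation HOXC4, HOXC8 and HOXC9 each overlap HOXC6, HOXB9 overlaps HOXB7, and HOXD4 overlaps HOXD3, so their levels depend on how shared reads were assigned.

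Of 5 ventral progenitor factors, 3 rose, and OLIG2 and NKX6-1 did not pass. Their median log2 change was 4.41, or 1.97 with uncounted genes at their bound, and the camera call (adjusted p = 0.018) was lost with an estimated correlation (adjusted p = 0.18) and with TPM (0.14). NKX6-2, which overlaps INPP5A, rose from 0.0815 ± 0.046 to 9.72 ± 1.3 CPM. Of 18 pan-neuronal genes, 4 rose and 7 fell (camera adjusted p = 0.55), and STMN2, a growth-associated gene of neurons, fell from 249.9 ± 12 to 6.33 ± 0.32 CPM. Of 14 somatic motor neuron genes 3 rose and 4 fell (adjusted p = 0.95), and 2 of 4 visceral motor neuron genes rose (0.3). Of 10 floor plate and p3 genes 4 rose and 1 fell, or 3 and 1 over the list alone (adjusted p = 0.069). Of 11 other interneuron genes 2 rose and 3 fell (0.95).

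Markers of other tissues also divided. Of 9 neural crest and roof plate genes 3 rose and 4 fell (camera adjusted p = 0.95), or 4 and 4 over the list alone. Of 8 mesoderm genes 1 rose and 4 fell (0.49), of 8 endoderm and endothelium genes 5 rose and 2 fell (0.24), and 4 of 5 non-neural ectoderm genes fell (0.075). Of 14 gliogenic genes 2 rose and 6 fell (0.44). Of 8 oligodendrocyte genes 1 rose and 4 fell (0.14). Of the 8 genes of early progenitor age 4 rose and 2 fell (1), and of 5 genes of late progenitor age 2 rose and 3 fell (1).

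Of 24 S and G2/M phase genes, 18 rose and none fell, with the proliferation marker MKI67 going from 514 ± 39 to 1236 ± 32 CPM and CENPF from 561 ± 12 to 1147 ± 44 CPM. Their camera call (adjusted p = 8.5e-05) was lost at an adjusted p = 0.35 with an estimated correlation. All 15 cholesterol synthesis genes fell (camera adjusted p = 3.4e-10, and 0.021 with an estimated correlation), among them HMGCS1 (1230.3 ± 14 to 516 ± 27 CPM) and INSIG1 (173 ± 4.2 to 51.1 ± 1 CPM). Of 31 proteasome subunit genes 17 rose and 3 fell, by a median of 0.13 (camera adjusted p = 0.03, lost at an adjusted p = 0.54 with an estimated correlation). Of 12 immediate early genes 5 rose and 4 fell (0.52), with JUN rising from 1.09 ± 0.21 to 30.5 ± 1.6 CPM and EGR1 falling from 17.2 ± 4.3 to 3.81 ± 0.72 CPM. Of 12 hypoxia and glycolysis genes 4 rose and 5 fell (0.95), and the glucose transporter SLC2A1 rose from 304 ± 10.4 to 852 ± 10.4 CPM. Of 13 p53 target genes 2 rose and 6 fell (0.83).

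In this stage the median, mean and camera direction differed in sign for HOX groups 1 to 4, the pan-neuronal genes and both progenitor age lists.

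The comparison of day 4 with day 1 addresses patterning along the dorsoventral axis and the start of neuron formation. OLIG2, the factor that marks motor neuron progenitors (ENSG00000205927, chromosome 21, 33025845 to 33029196), rose from 3.54 ± 0.35 to 62.5 ± 4.8 CPM, a log2 change of 4.15 ± 0.16 (adjusted p = 8.8e-22). NKX6-1, which marks the ventral neural tube, rose from 11.7 ± 0.29 to 126 ± 12 CPM (3.42 ± 0.15, adjusted p = 2.2e-19). STMN2, which had fallen on day 1, rose from 6.33 ± 0.32 to 193 ± 6.7 CPM. POU5F1 fell from 10.2 ± 0.69 to 0.0469 ± 0.016 CPM. In all, 4574 genes were higher and 4435 lower on day 4, and 1403 and 1173 of these changed at least 2-fold.

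Among the genes with the largest rises, OLIG1 rose from 0.948 ± 0.05 to 58.6 ± 6.3 CPM, and the neuronal zinc finger factor ST18 from 0.165 ± 0.088 to 53.6 ± 3.4 CPM. The synaptotagmin gene SYT4 rose from 0.124 ± 0.054 to 19.5 ± 1.1 CPM. SHISA3, THSD7A and PPP1R17 rose by 6.86 ± 0.39, 7.36 ± 0.5 and 6.98 ± 0.3 on the log2 scale. FEZF2 went back to 0.0452 ± 0.078 CPM, a ratio of 796 (counting interval 272 to 3862). HES3, a repressor of early neural progenitors, fell from 37.9 ± 1.9 to 0.368 ± 0.11 CPM, and the apolipoprotein gene APOE from 79.9 ± 2.4 to 0.912 ± 0.033 CPM. VRTN fell from 46.7 ± 0.98 to 0.158 ± 0.066 CPM, CA4, a carbonic anhydrase gene, from 51.3 ± 1.5 to 1.05 ± 0.53 CPM, and the troponin gene TNNC1 from 22.5 ± 1.3 to 0.288 ± 0.085 CPM. TMPRSS2, a membrane serine protease gene, was 21.3 ± 1.5 CPM on day 1 and 0.0407 ± 0.046 on day 4.

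All 5 ventral progenitor factors rose (camera adjusted p = 3.9e-06, and 0.018 with an estimated correlation). Of 18 pan-neuronal genes, 16 rose and none fell, among them ELAVL4 (2.09 ± 0.21 to 61.9 ± 3.5 CPM) and ELAVL3 (5.31 ± 0.43 to 87.7 ± 4.4 CPM). The list's call (camera adjusted p = 4.9e-12) was lost at an adjusted p = 0.12 with an estimated correlation. Of 13 neurogenic genes 7 rose and 2 fell, or 7 and 3 over the list alone (camera adjusted p = 0.011, lost at an adjusted p = 0.4 with an estimated correlation). NEUROD4 rose from 8.37 ± 0.49 to 91.2 ± 3 CPM and NHLH1 from 1.21 ± 0.11 to 41.7 ± 3.7 CPM. The 2 that fell were MFNG, a glycosyltransferase that modifies Notch, and GADD45G. Of 7 Notch target genes 5 rose, or 6 over the list alone, with HES1 going from 6.29 ± 0.43 to 15.9 ± 1.3 CPM (camera adjusted p = 0.018, lost at an adjusted p = 0.27 with an estimated correlation). The 12 neural progenitor genes divided into 6 that rose and 5 that fell (camera adjusted p = 0.48).

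Of 14 somatic motor neuron genes 7 rose and 1 fell, or 7 and 2 over the list alone. PRPH, the gene of the neurofilament protein peripherin, rose from 0.59 ± 0.11 to 22 ± 1.3 CPM, and the LIM factor LHX4, which overlaps ACBD6, from 0.915 ± 0.41 to 19.1 ± 1.3 CPM. LHX3 stood at 3.31 ± 0.64 CPM on day 4, a ratio of 92.7 (counting interval 31.4 to 452). The gene that fell was FOXP1, and the list's call (camera adjusted p = 3.4e-05) was lost at an adjusted p = 0.11 with an estimated correlation. Of 4 visceral motor neuron genes 3 rose (camera adjusted p = 0.0032, and 0.02 with an estimated correlation; 0.058 with TPM). Of 11 other interneuron genes 8 rose and LBX1 fell, or 9 and 1 over the list alone (camera adjusted p = 7.2e-05, and 0.0032 with an estimated correlation). The sensory and dorsal factor POU4F1 rose from 0.0765 ± 0.049 to 3.97 ± 0.2 CPM, and EN1, which marks V1 interneurons, reached 1.41 ± 0.36 CPM, a ratio of 116 (counting interval 20.4 to 4620.2).

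Of 9 neural crest and roof plate genes 6 fell and none rose (camera adjusted p = 0.00036, and 0.0076 with an estimated correlation). MSX1 fell from 21.8 ± 2 to 2.58 ± 0.38 CPM and PAX3, which overlaps CCDC140, from 3.81 ± 0.36 to 0.528 ± 0.17 CPM. Of 11 neuromesodermal progenitor genes 9 fell and none rose (camera adjusted p = 7.8e-07, and 0.013 with an estimated correlation), with CDX1 going from 9.39 ± 0.39 to 0.0726 ± 0.035 CPM. CRABP2, a cellular RA-binding protein gene, fell from 1326 ± 28 to 488 ± 52 CPM, and the RA-responsive list had 1 member higher and 4 lower of 10 (camera adjusted p = 0.25). Among 7 pluripotency genes 4 fell and 2 rose (0.079). Those that rose were LIN28A, to 893 ± 13 CPM, and PRDM14, from 0.0221 ± 0.038 to 0.984 ± 0.33 CPM, a ratio of 39.3 (counting interval 10.5 to 330.3).

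Most HOX genes of groups 1 to 4 and 5 to 8 rose. In groups 1 to 4, 10 of 12 rose and 2 fell, HOXD1 among them. That list's call (camera adjusted p = 5.5e-07) held with an estimated correlation (adjusted p = 0.019). In groups 5 to 8, 9 of 11 rose and none fell (camera adjusted p = 3.1e-09, and 0.0076 with an estimated correlation), and HOXA7 and HOXC8 did not pass. HOXC6 rose from 1.03 ± 0.29 to 11.8 ± 1.3 CPM, HOXD8 from 0.92 ± 0.25 to 9.54 ± 0.23 CPM and HOXC4 from 10.3 ± 0.94 to 51.7 ± 4.3 CPM. In groups 9 to 13 HOXB9 rose from 134 ± 0.46 to 503 ± 26 CPM and the other 3 did not pass (camera adjusted p = 0.21).

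Of 24 cell cycle genes 22 fell and none rose, or 23 over the list alone, with RRM2 going from 423 ± 9.3 to 242 ± 6.7 CPM (camera adjusted p = 1.1e-07, lost at an adjusted p = 0.2 with an estimated correlation). Of 12 immediate early genes 10 rose, or 11 over the list alone, with EGR1 going from 3.81 ± 0.72 to 39.8 ± 2.6 CPM (camera adjusted p = 2.5e-05, lost at an adjusted p = 0.17). Of 13 p53 target genes 9 rose and TP53I3 fell, and the cell cycle inhibitor CDKN1A rose from 49.6 ± 0.87 to 112 ± 7.7 CPM (camera adjusted p = 0.011, lost at an adjusted p = 0.38 with an estimated correlation). Of 15 cholesterol genes 10 rose, or 11 over the list alone, with LSS going from 174 ± 2.1 to 247 ± 10.1 CPM (camera adjusted p = 0.015, lost at an adjusted p = 0.35 with an estimated correlation). The median, mean and camera direction differed in sign for the mesoderm, gliogenic and early progenitor age lists. The deposited TPM values gave fewer genes lower on day 4 (2792), and 64.1% of their calls were higher, against 50.8% with counts.

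The comparison of day 8 with day 4 addresses motor neuron differentiation. ISL2, a LIM factor of motor neurons, rose from 0.115 ± 0.021 to 14.2 ± 0.37 CPM, a log2 change of 6.87 ± 0.44 (adjusted p = 1.1e-16). MNX1 (HB9), a defining factor of motor neurons (ENSG00000130675, chromosome 7, 156994051 to 157010651), rose from 1.13 ± 0.21 to 23.8 ± 2.1 CPM, and ISL1 from 0.499 ± 0.21 to 12.6 ± 1.1 CPM. The neurofilament gene NEFM rose from 86.5 ± 1.9 to 1461 ± 96 CPM (4.08 ± 0.21, adjusted p = 5.7e-17). In all, 5224 genes were higher and 5076 lower on day 8, while 1926 were higher and 678 lower by at least 2-fold.

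Other genes with the largest rises were EEF1A2, the neuron and muscle form of an elongation factor (1.44 ± 0.22 to 42.4 ± 1.5 CPM), and MEGF10, an engulfment receptor gene (1.69 ± 0.26 to 77.4 ± 1.5 CPM). The neuropeptide gene SST rose from 0.248 ± 0.1 to 10.2 ± 1.1 CPM, the receptor gene TACR1 from 0.121 ± 0.12 to 10.6 ± 0.26 CPM and LEFTY2, a Nodal inhibitor, from 0.182 ± 0.038 to 13.4 ± 3.3 CPM. SCML4 and PALMD rose by 7.7 ± 0.44 and 5.16 ± 0.34 on the log2 scale. RELN, an extracellular guide of neuron migration, fell from 1839 ± 121 to 247 ± 18 CPM, and ROBO3, a receptor of commissural axons, from 97.6 ± 4.2 to 14.1 ± 1.2 CPM. The basement membrane gene NID2, which overlaps RTRAF, fell from 208 ± 11 to 23.8 ± 0.43 CPM. FAP fell from 12.7 ± 1.4 to 0.699 ± 0.3 CPM, SCUBE2, which helps release Hedgehog ligand, from 16.6 ± 0.67 to 2.23 ± 0.34 CPM, and KLHL14 and ST8SIA5 had log2 changes of -3.21 ± 0.13 and -2.57 ± 0.11.

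Of 14 somatic motor neuron genes 11 rose and PRPH fell, by a median of 3.01 (camera adjusted p = 1.4e-06, lost at an adjusted p = 0.056 with an estimated correlation). Genes of acetylcholine handling were among them: the transporter gene SLC5A7 rose from 0.235 ± 0.017 to 7.21 ± 0.59 CPM and CHAT, which overlaps SLC18A3, from 0.135 ± 0.043 to 3.44 ± 0.2 CPM. All 18 pan-neuronal genes rose (camera adjusted p = 1.9e-12, lost at an adjusted p = 0.11 with an estimated correlation). NEFL rose from 103 ± 3.9 to 1053 ± 27 CPM and GAP43 from 20.9 ± 3.2 to 108 ± 5 CPM. Of 12 neural progenitor genes 9 fell, and SOX21, FABP7 and MSI1 rose (camera adjusted p = 0.011, lost at an adjusted p = 0.2 with an estimated correlation). PAX6 fell from 347 ± 17 to 134 ± 1.1 CPM and HES5 from 166 ± 18 to 44 ± 3.6 CPM. Of 13 neurogenic genes 9 rose and 4 fell (0.16), among them DLL3, a Notch ligand gene, from 67 ± 4.4 to 147 ± 11 CPM.

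Of 10 floor plate and p3 genes 8 rose, with SHH going from 1.47 ± 0.25 to 16.5 ± 1.1 CPM and FOXA2 from 0.241 ± 0.054 to 3.41 ± 0.56 CPM (camera adjusted p = 0.00038, lost at an adjusted p = 0.2 with an estimated correlation). Of 7 Hedgehog targets these floor plate genes, FOXA2, NKX2-2 and NKX2-8, rose and the other 4 fell (0.69), with HHIP going from 17.1 ± 0.72 to 3.97 ± 0.42 CPM and GLI1 from 49.1 ± 5.4 to 24.2 ± 1.6 CPM. The call of NKX2-2 was lost without replicate 1. Of 14 gliogenic genes 7 rose and none fell (camera adjusted p = 0.018, and 0.046 with an estimated correlation). NFIA, a factor of gliogenesis and of late-born neurons, rose from 0.126 ± 0.035 to 2.46 ± 0.47 CPM and the endothelin receptor gene EDNRB from 3.46 ± 0.33 to 14.4 ± 0.91 CPM. On day 0 NFIA and NFIB had stood at 2.25 ± 0.24 and 2.32 ± 0.34 CPM, so on day 8 they were near the level of the starting cells. Of 8 oligodendrocyte genes 5 rose and SOX8 fell (camera adjusted p = 0.025, lost at an adjusted p = 0.068 with an estimated correlation). MBP, a myelin gene, rose from 0.976 ± 0.4 to 3.84 ± 0.42 CPM. Of the same list, SOX10 stood at only 0.0188 ± 0.033 CPM on day 8. PDGFRA was 1.2 ± 0.2 CPM on day 4 and 1.22 ± 0.14 CPM on day 8.

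Of the 8 genes of early progenitor age 7 fell and IGF2BP3 did not pass (camera adjusted p = 5.1e-06, and 0.019 with an estimated correlation). PRTG fell from 2592 ± 398 to 414 ± 33 CPM, LIN28A from 893 ± 13 to 267 ± 13 CPM and TRIM71 from 481 ± 39.9 to 191 ± 9.3 CPM. Of 5 genes of late progenitor age NFIA, NFIB and POU2F2 rose and ZFHX3 fell, with POU2F2, a factor of late-born spinal neurons, going from 2.89 ± 0.19 to 57.5 ± 2.1 CPM. The late list's call (camera adjusted p = 0.047) was lost with an estimated correlation (adjusted p = 0.11), without replicate 3 (0.093), with the replicate block (0.051) and with TPM (0.13). The call of ZFHX3 was lost without replicate 2 (0.57), without the filter on low counts (0.074), in a fit of the 2 days alone (0.1) and with TPM (0.35). All 11 HOX genes of groups 5 to 8 rose (camera adjusted p = 1.7e-05, and 0.043 with an estimated correlation), with HOXC6 going from 11.8 ± 1.3 to 65.2 ± 3 CPM and HOXC8 from 0.719 ± 0.2 to 5.57 ± 0.39 CPM.

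All 24 cell cycle genes fell, with MKI67 going from 978 ± 77 to 514 ± 25 CPM (camera adjusted p = 8.1e-13, lost at an adjusted p = 0.096 with an estimated correlation). Of 31 proteasome genes 24 fell and none rose, by a median log2 change of -0.21 (camera adjusted p = 8.3e-06, lost at an adjusted p = 0.25 with an estimated correlation). All 15 cholesterol genes rose (camera adjusted p = 3e-08, and 0.043 with an estimated correlation), with HMGCS1 going from 647 ± 32 to 1140.5 ± 107 CPM. SLC2A1 fell from 874 ± 75 to 349 ± 14 CPM. The median, mean and camera direction differed in sign for the Hedgehog target, non-neural ectoderm and p53 target lists. With TPM and limma, where the median gene moved by 0.109 on the log2 scale, 3015 genes were lower, and 65.6% of the calls were higher against 50.7% with counts.

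The comparison of day 15 with day 8 addresses maturation and the later progenitors. LIN28A (ENSG00000131914, chromosome 1, 26410778 to 26429722) fell from 267 ± 13 to 18.7 ± 2.3 CPM, a log2 change of -3.84 ± 0.07 (adjusted p = 4.2e-32). NFIA (ENSG00000162599, chromosome 1, 60865259 to 61462793) rose from 2.46 ± 0.47 to 57.4 ± 1.4 CPM (4.53 ± 0.18, adjusted p = 1e-21). OLIG2 fell from 93.7 ± 5.1 to 24.9 ± 4.5 CPM and ISL2 from 14.2 ± 0.37 to 1.17 ± 0.76 CPM, while SHH rose from 16.5 ± 1.1 to 123 ± 47 CPM. In all, 4989 genes were higher and 5064 lower on day 15, and 1526 and 892 changed at least 2-fold.

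Among the largest rises was the complement inhibitor gene CFI, which was not counted on day 8 and stood at 12.4 ± 5.3 CPM on day 15, at least 421-fold higher. The copper-binding plasma protein gene CP, which overlaps HPS3, rose from 0.181 ± 0.084 to 26.2 ± 13 CPM, the clotting factor gene F5 from 0.218 ± 0.072 to 14.6 ± 4.2 CPM and the tetraspanin-like gene TM4SF1 from 0.0695 ± 0.061 to 13.7 ± 4 CPM. CFAP126, a cilium gene that overlaps SDHC, rose from 0.129 ± 0.011 to 11.6 ± 4.1 CPM, and the dopamine receptor gene DRD1 from 0.178 ± 0.044 to 13.1 ± 4.5 CPM. EVA1C and the transporter gene SLC16A12 rose by 6.18 ± 0.29 and 5.7 ± 0.34 on the log2 scale. The melanosome gene PMEL, which overlaps CDK2, fell from 63.1 ± 2.5 to 4.71 ± 0.88 CPM, the neurogenic factor NHLH2 from 17 ± 2 to 1.32 ± 0.19 CPM and SHISA3 from 53.7 ± 6.8 to 5.35 ± 0.67 CPM. The collagen gene COL1A2 and SCML4 had log2 changes of -3.21 ± 0.27 and -3.2 ± 0.23.

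Of 13 neurogenic genes 11 fell and none rose (camera adjusted p = 4.4e-07, lost at an adjusted p = 0.11 with an estimated correlation). NEUROG2 fell from 89.9 ± 4.7 to 21.9 ± 4.2 CPM and NEUROG1 from 35.4 ± 1.1 to 6.7 ± 2 CPM. Of 7 Notch targets 5 fell, and HES1 and HEY1 rose (camera adjusted p = 0.023, lost at an adjusted p = 0.29 with an estimated correlation). HES5 fell from 44 ± 3.6 to 5.23 ± 1.4 CPM and HEYL from 20.2 ± 1.3 to 2.01 ± 0.73 CPM, whereas HES1 rose from 32.1 ± 1.8 to 83.9 ± 13 CPM. Of 12 neural progenitor genes 7 fell, and FABP7 and PROM1 rose (camera adjusted p = 0.013, lost at an adjusted p = 0.2 with an estimated correlation). SOX3 fell from 221 ± 13 to 35.8 ± 6.4 CPM and NES, the gene of the intermediate filament nestin, from 2590.2 ± 71 to 1083 ± 82 CPM. Of 5 ventral progenitor factors 4 fell and NKX2-2 rose (0.066).

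Motor neuron genes moved apart. Of 14, 5 rose and 8 fell (camera adjusted p = 0.37). Those that rose were CHAT, SLC18A3, SLC5A7, FOXP1 and ALDH1A2, which serve acetylcholine handling or mark limb-level and RA-producing motor neurons, and SLC5A7 went from 7.21 ± 0.59 to 35.8 ± 3.2 CPM. The early factors ISL2, LHX4 and MNX1 fell, MNX1 from 23.8 ± 2.1 to 6.95 ± 2.5 CPM and LHX4 from 89.5 ± 3.7 to 24.8 ± 6 CPM. PHOX2A, a factor of hindbrain visceral motor neurons, fell from 1.9 ± 0.34 to 0.114 ± 0.024 CPM, in a visceral motor neuron list with 1 higher and 2 lower of 4 (0.23). Of 18 pan-neuronal genes 4 rose and 8 fell (0.44), with TUBB3 going from 1499 ± 92 to 923 ± 123 CPM.

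All 10 floor plate and p3 genes rose (camera adjusted p = 8.8e-07, lost at an adjusted p = 0.092 with an estimated correlation), with FOXA2 going from 3.41 ± 0.56 to 27.5 ± 8 CPM. Of 14 gliogenic genes 8 rose and 4 fell. NFIB rose from 1.95 ± 0.43 to 39 ± 4.5 CPM, S100B from 0.0777 ± 0.086 to 3.03 ± 0.078 CPM and the glutamate transporter gene SLC1A3 from 40.6 ± 2.1 to 183 ± 51 CPM. GFAP, SPARCL1, EDNRB and FGFR3, which mark astrocytes or their precursors, fell, GFAP from 0.231 ± 0.094 to 0.0519 ± 0.049 CPM. The gliogenic call (camera adjusted p = 0.042) was lost with an estimated correlation (adjusted p = 0.092), without replicate 1 (0.061), without replicate 3 (0.05) and with TPM (0.051). Of 8 oligodendrocyte genes MBP rose and 3 fell (0.11).

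All 8 genes of early progenitor age fell (camera adjusted p = 1.7e-11, and 0.0031 with an estimated correlation), with TRIM71 going from 191 ± 9.3 to 28.3 ± 2.7 CPM and LIN28B from 98 ± 3.3 to 26.1 ± 0.41 CPM. Of 7 pluripotency genes, which share LIN28A with that list, 4 fell, or 5 over the list alone (camera adjusted p = 0.0017, and 0.019 with an estimated correlation). DPPA4 fell from 79.8 ± 1.7 to 31.9 ± 5.4 CPM and DNMT3B, a DNA methyltransferase gene, from 72.8 ± 4 to 30.9 ± 3.5 CPM. PRDM14 also fell, but its call was lost without replicate 1 (0.41), without replicate 3 (0.33), without the filter on low counts (0.076) and with DESeq2 (0.08). POU5F1 was near 0 on both days, at 0.0206 ± 0.018 CPM on day 8 and 0.0281 ± 0.029 on day 15. Of 5 genes of late progenitor age NFIA, NFIB and NFIX rose and ZFHX3 fell. NFIX rose from 0.157 ± 0.086 to 8.67 ± 1.8 CPM, and the list's call (camera adjusted p = 0.042) was lost with an estimated correlation (adjusted p = 0.11) and without replicate 1 (0.061). In HOX groups 9 to 13, 3 of 4 rose, or 4 over the list alone, with HOXB9 reaching 1041 ± 88 CPM. Their call (camera adjusted p = 0.047) was lost with an estimated correlation (adjusted p = 0.21), without replicate 1 (0.057) and without replicate 3 (0.09). HOXC8, in groups 5 to 8, rose from 5.57 ± 0.39 to 53.9 ± 2.8 CPM.

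RA-related genes also moved apart, with 4 higher and 5 lower of 10 (camera adjusted p = 0.5). CYP26A1 rose from 2.46 ± 0.46 to 15.9 ± 3.9 CPM and CYP26B1, another RA-degrading enzyme gene, from 0.537 ± 0.29 to 17.8 ± 13 CPM, but on day 14 they stood at 4.02 ± 0.37 and 4.47 ± 1.7 CPM. CRABP2 fell from 370.3 ± 21 to 53.5 ± 7.6 CPM, with 68.6 ± 2.9 CPM on day 14. Of 24 cell cycle genes 23 fell, with MCM7 going from 434 ± 18 to 242 ± 8.4 CPM (camera adjusted p = 4.8e-12, lost at an adjusted p = 0.11 with an estimated correlation). Of 12 immediate early genes 6 fell, or 7 over the list alone, with EGR1 going from 65.2 ± 4.7 to 25.6 ± 3.4 CPM. That list's call (camera adjusted p = 0.029) was lost with an estimated correlation (adjusted p = 0.47) and without replicate 2 (0.11). Of 15 cholesterol genes 9 fell (camera adjusted p = 0.005, lost at an adjusted p = 0.28 with an estimated correlation). Of 31 proteasome genes 17 fell, or 18 over the list alone, by a median log2 change of -0.13 (camera adjusted p = 0.0054, lost at an adjusted p = 0.48 with an estimated correlation and 0.078 with TPM). The median, mean and camera direction differed in sign for the mesoderm and RA-responsive lists.

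Over all 4 stages camera called 51 list results, and 18 of them held with an estimated correlation. These were, on day 1, pluripotency, neuromesodermal progenitor, neural progenitor, neurogenic and cholesterol genes. On day 4 they were neuromesodermal progenitor genes, HOX groups 1 to 4 and 5 to 8, ventral progenitor, visceral motor neuron, other interneuron and neural crest genes. Those on day 8 were HOX groups 5 to 8, gliogenic, cholesterol and early progenitor age genes, and those on day 15 were pluripotency and early progenitor age genes.

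**Figure D3:**
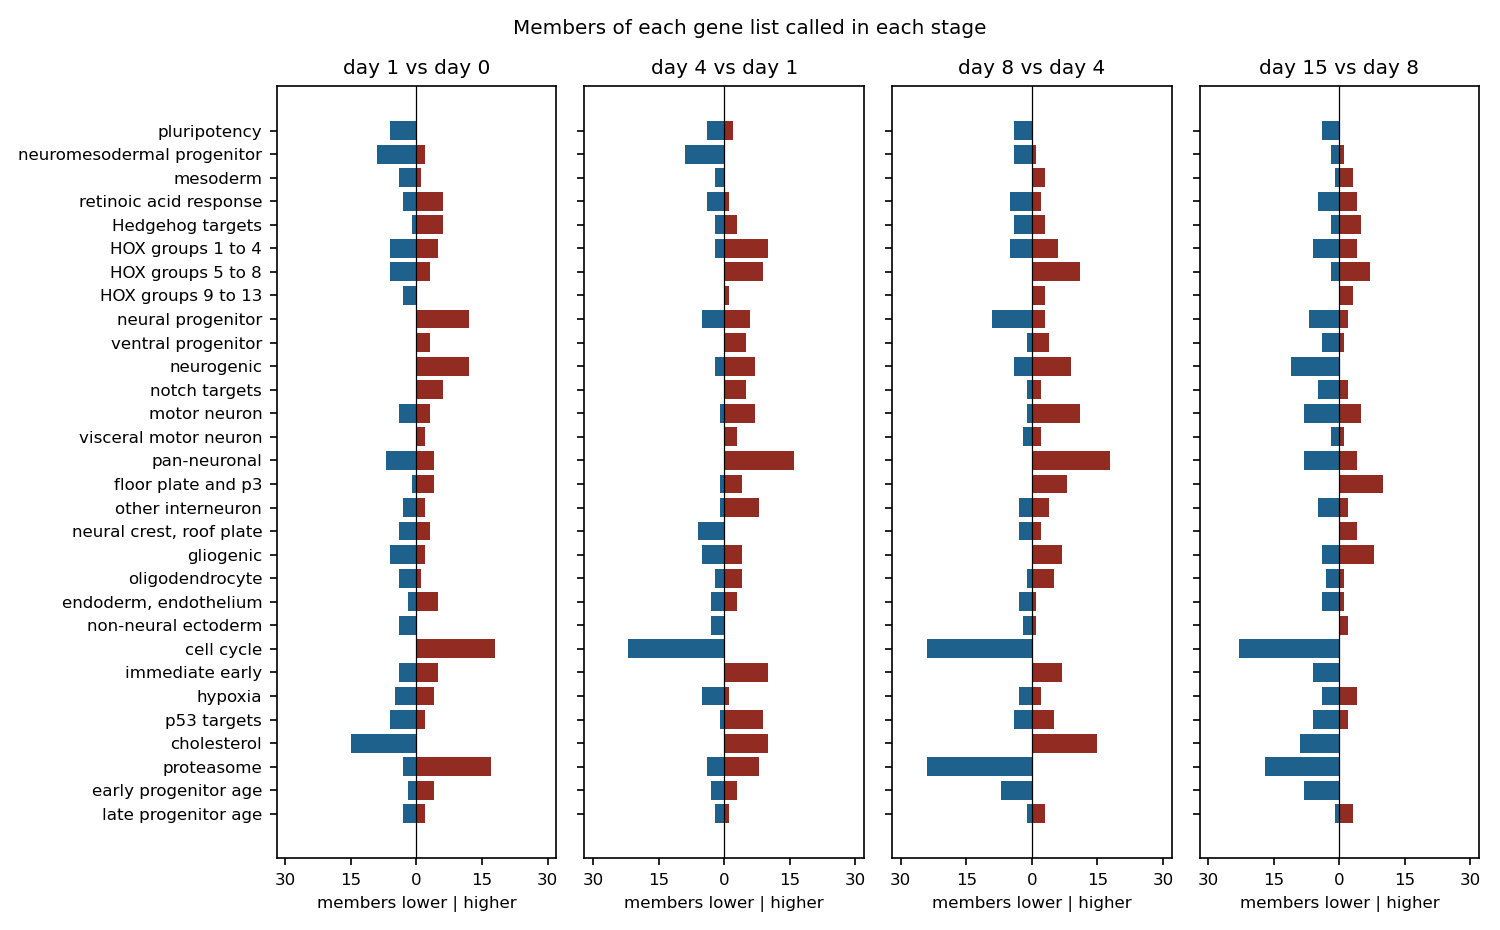
Number of members of each of the 30 gene lists called higher (red, to the right) or lower (blue, to the left) on the later day of each stage, with 1 list per line and 1 stage per panel. All 12 neural progenitor genes rose on day 1, all 18 pan-neuronal genes on day 8 and all 10 floor plate and p3 genes on day 15.

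A panel of 46 genes was followed over every day, and NANOG, a pluripotency factor, was below the filter on low counts. POU5F1 had dropped to 1.63 ± 0.032 CPM by day 2 and was not counted in any library on day 5. PAX6 was highest on day 2 at 518 ± 2.2 CPM, above day 1 (adjusted p = 2e-06). NKX6-1 and OLIG2 first passed on day 2, at an adjusted p under 0.05 and a change of at least 2-fold from day 0. OLIG2 was highest on day 7 at 96.2 ± 7.2 CPM, which did not differ detectably from day 8 (adjusted p = 0.89) and lay above day 15 (adjusted p = 2.6e-16). NEUROG2 was highest on day 5 at 158 ± 4.2 CPM, not separable from day 4 (adjusted p = 0.89). SOX2, a factor of pluripotent and neural progenitor cells, never reached a 2-fold change from day 0.

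MNX1, ISL1 and LHX3 were highest on day 8, at 23.8 ± 2.1, 12.6 ± 1.1 and 18 ± 1.6 CPM. None of the 3 differed detectably from its next highest day (adjusted p = 0.41, 0.34 and 0.6), and all were lower on day 15 (adjusted p = 1.9e-08, 4.7e-08 and 1e-09). TUBB3 and STMN2 were highest on day 9, at 1563 ± 79.6 and 1013 ± 58 CPM. SLC18A3, the vesicular acetylcholine transporter gene, was highest on day 13 at 52.8 ± 3.8 CPM and CHAT on the same day at 8.25 ± 0.81 CPM. FOXA2 was highest on day 14 at 30.4 ± 3 CPM, and NFIA and NFIB on day 15 at 57.4 ± 1.4 and 39 ± 4.5 CPM. MKI67 went from its highest level on day 1, 1236 ± 32 CPM, to 355 ± 17 CPM on day 15. MKI67, TUBB3, SLC18A3, CHAT and FOXA2 were not separable from their next highest day (adjusted p = 0.71, 0.69, 0.69, 0.83 and 0.7), whereas NFIA and NFIB lay above day 14 (adjusted p = 0.019 and 0.036).

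The day on which a panel gene first passed depended on the replicates for some genes. A first pass can be a rise or a fall from day 0. It was a fall for FOXA2, NFIA and SOX10, and a rise for the other genes named in this paragraph. Without replicate 1, or without replicate 2, NKX2-2 and FOXA2 moved from day 1 to day 4, LHX3 from day 2 to day 4 and NHLH1 from day 1 to day 2. Without any 1 of the replicates CHAT moved from day 4 to day 5. MNX1 moved from day 5 to day 4 without replicate 2 and with DESeq2, and SIM1, a factor of p3-derived neurons, from day 10 to day 12 without replicate 2 or 3. HOXB4 moved from day 9 to day 5 and NFIA from day 1 to day 2 without replicate 2. SLC1A3 moved from day 11 to day 10 without replicate 1 and to day 12 without replicate 2, and SOX10 from day 1 to day 2 with DESeq2. Requiring a log2 change of at least 2 from day 0 moved 6 first days and left 31 of 43 the same.

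**Figure D4:**
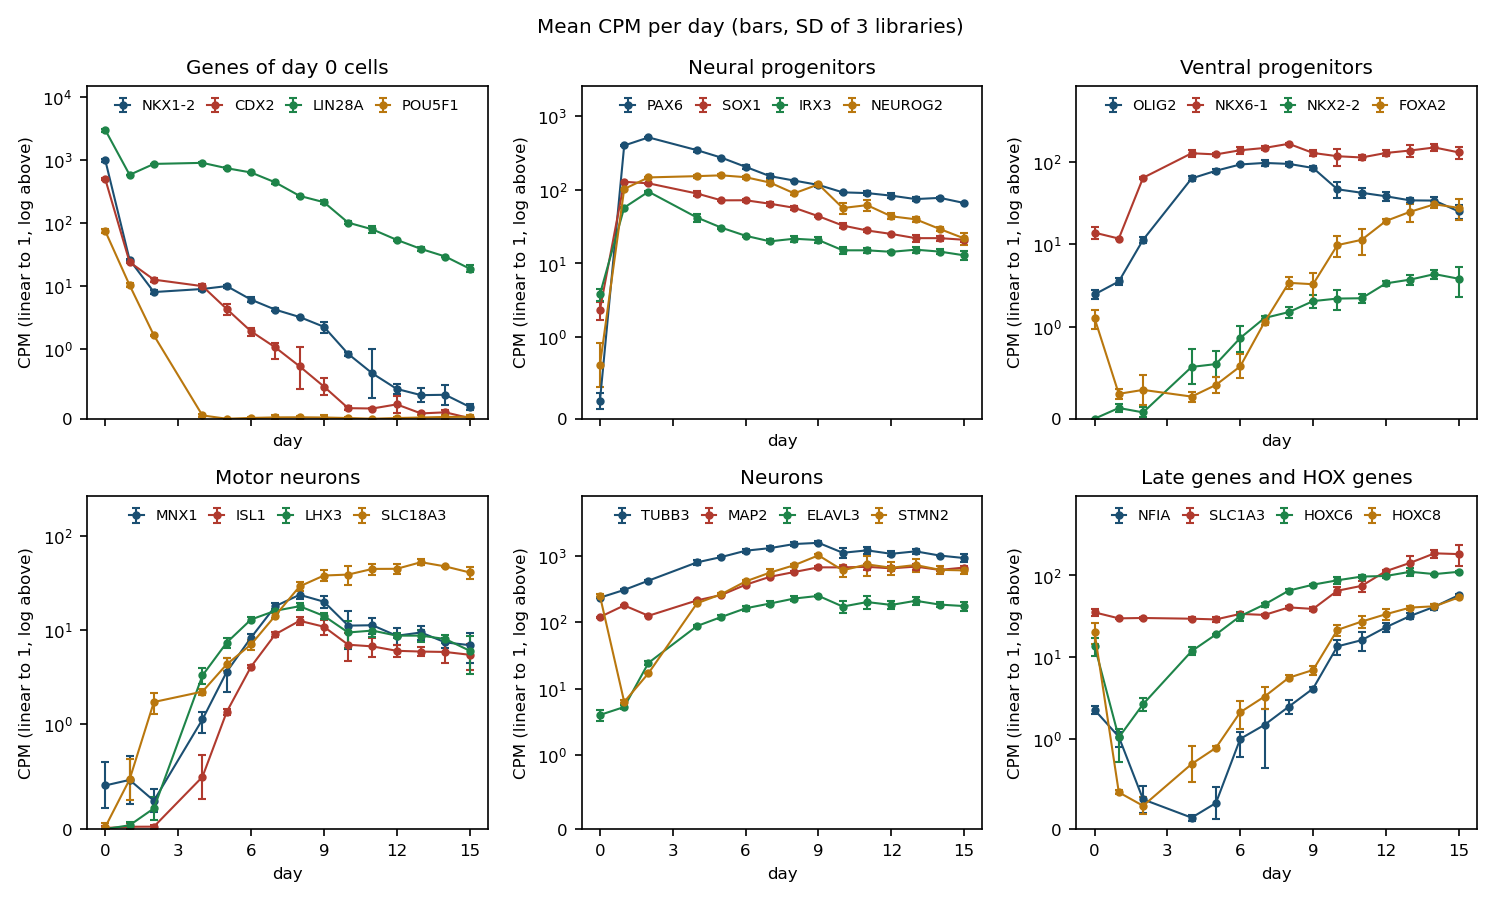
Mean CPM (vertical axis, linear up to 1 and logarithmic above) against day for 24 genes of the panel, with the SD of 3 libraries as error bars. NKX1-2 and POU5F1 drop within days of day 0, PAX6 is highest on day 2, MNX1 on day 8 and NFIA on day 15.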

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

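The use of day 14 in place of day 15 was chosen only after the alternation of odd and even days had been seen, and all other settings were set beforehand. Requiring a change of at least 2-fold lowered the counts by construction. On day 1, 1995 genes were then higher and 2003 lower. On day 4 these were 1403 and 1173, on day 8 1926 and 678, and on day 15 1526 and 892. With the deposited TPM and limma, 2792 genes were lower on day 4 and 3015 on day 8, and the cause was not tested. The other counts of the 4 stages and of all days stayed within 1.5 times their reported values with DESeq2, its size factors, no filter and TPM, and so did the stage counts in fits of each pair of days alone. Against day 14, 4392 genes were higher and 4263 lower than on day 8. No named gene or list call reversed in these settings. The larger direction did change where the counts lay close. On day 4 it was the lower genes with the size factors of DESeq2 (4433 and 4645) and with DESeq2 itself (4512 and 4555), and on day 15 the higher genes without the filter (4939 and 4556), with TPM and limma (4746 and 3530), in the fit of the 2 days alone (4626 and 4605), with a 2-fold change, against day 14, and without any 1 library of day 15 or replicate 1 or 3 of day 8. Positions on the first component moved by more than the spread of their day on 5 days with 500 genes, 11 with 5000 and 10 with TPM, out of 13. Day 1 stood at 7.8% with 500 genes, 4.3% with 5000 and 5.4% with TPM, day 4 at 40.4%, 38% and 37.2%, day 8 at 80.4%, 77.7% and 79%, and day 14 at 99.3%, 98.8% and 98.8%.

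Leaving out replicates gave fewer calls, with fewer libraries in the fit. Without a replicate number, or without a single library of the stage, the count of genes higher on day 1 ran from 4733 to 5618 and of genes lower from 5195 to 5900. On day 4 these ran from 3536 to 4286 and from 3146 to 4090, on day 8 from 4114 to 4954 and from 3977 to 4685, and on day 15 from 3790 to 4770 and from 4139 to 4699. Across all days the count ran from 16656 to 17202 without a replicate number.

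With a replicate block, a term for the replicate number, 5773 genes were higher and 6169 lower on day 1, 4603 and 4437 on day 4, 5239 and 5093 on day 8, and 5015 and 5071 on day 15, with 17921 across all days. The numbers do not pair the libraries. Deviations from the day means had a mean correlation of 0.002 between days for libraries with the same number and -0.001 for other numbers, and 6 of 12 libraries matched their own number best.

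Of 480 named gene results, 52 lost their call in at least 1 setting. Of 51 list calls, 33 were lost with an estimated correlation, 6 with TPM, 1 with the replicate block, and 3, 2 and 4 without replicate 1, 2 and 3. The fit of TPM with limma, which changed the values, tool, scale and filter together, also moved the balance of the calls, with 64.1% of them higher on day 4, 65.6% on day 8 and 57.3% on day 15, against 50.8%, 50.7% and 49.6% with counts and edgeR. Depth limits genes near the floor of 3 counts, for which the simulation held no changed genes. Among simulated genes above that floor, 1.5-fold changes were called for 76%.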

Other observations

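The comparison of odd with even days, with its windows of days, and that of neighbouring days were not among the planned comparisons. Their p-values are not adjusted for the choice of these patterns from the same data. For the alternation of odd and even days, the tests of the step, of a medium change and of HOX genes were chosen only after the result was seen, and so were the tests of the step at day 10 except that of GC content and gene length. The pace of change was uneven between neighbouring days. From day 0 to day 1, 3998 genes changed at least 2-fold, and 1022 did so from day 1 to day 2. Between neighbouring days from day 4 on, 15 to 353 genes did, except from day 9 to day 10, when 772 rose and 231 fell. In that step the doublecortin gene DCX fell from 1609 ± 167 to 1012 ± 196 CPM and the matrix gene TNC rose from 161 ± 27 to 442 ± 178 CPM (n = 3). Of 30 lists, 3 were called with an estimated correlation as well and all were lower, HOX groups 1 to 4 (9 of 12 lower, camera adjusted p = 1.8e-10, and 0.0017 with an estimated correlation), genes of early progenitor age (7 of 8, 3.5e-07, and 0.0053) and RA-responsive genes (7 of 10 lower and 1 higher, 6.7e-06, and 0.0013). The first and last of these also alternated between odd and even days. Of 13 p53 target genes 11 rose (3e-06, lost at 0.12 with an estimated correlation), and so did 8 of 12 immediate early genes (3.6e-05, lost at 0.2).

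From day 9 on, CYP26A1 was higher on odd days. Its means on days 9 to 15 were 22, 6.16, 19.8, 5.55, 11.8, 4.02 and 15.9 CPM, and edgeR put odd over even days at 3.14-fold, a log2 difference of 1.65 ± 0.11 (adjusted p = 5.5e-12). CYP26B1 differed by 1.75 ± 0.19 and RARB by 0.48 ± 0.05. P-values for odd against even days, camera and comparisons of earlier with later days included, rest on the spread between libraries within a day. They do not measure the spread between days, so single days that lie off a smooth trend can be called as well. In all, 898 genes were higher and 1561 lower on odd days from day 9 to day 15, while 2 genes in all differed that way from day 4 to day 8 (edgeR). Of the 7 windows of days examined, 3 others gave 1638 and 2362 genes from day 8 to day 15, 278 and 366 from day 4 to day 9, and 1033 and 1429 from day 4 to day 15. A step from day 9 to day 10 enters all windows with both days, and 375 and 798 genes were left from day 10 to day 15 and 118 and 203 from day 11 to day 15.

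Of 10 RA-responsive genes 7 were higher on odd days from day 9 to day 15 and STRA6 was lower (camera adjusted p = 5.1e-11, and 5.9e-06 with an estimated correlation). These values are adjusted over the lists, but not for the choice of the contrast and its window, which were not planned. The step between day 9 and day 10 is argued against as the whole cause, since over days 10 to 15 the list was again higher on odd days (7 of 10, adjusted p = 2.3e-06 with an estimated correlation). Library size is argued against as the cause, since with every library thinned to the lowest total, 7 of the 7 were still called higher (12 libraries of odd and 9 of even days). A trend with GC content or gene length is argued against as the whole cause, since it held 0.6% of the variance, came to at most 0.19 in any gene on the log2 scale, and left the list's median at 0.42 when removed. A medium change every other day that acted alike from day 4 on stays open. Such a change would act by day, whereas the p-values that follow rest on the spread between libraries within a day. CYP26A1 was higher on day 5 (16.6 CPM) than on days 4 and 6 (9.65 and 5.9 CPM), but then only fell to day 8 (3.6 and 2.46 CPM). RARB on day 5 (61.9 CPM) lay between days 4 and 6 (69.6 and 50.9 CPM). The smallest camera p with an estimated correlation, multiplied by 6 comparisons of earlier and later days and 30 lists, was 0.0012 (more alternation on days 10 to 15 than on days 4 to 8). It was 0.0013 with day 9 among the later days and 0.0021 with days 8 and 9 among them, but 1 in each of the 3 comparisons with day 9 among the earlier days. RA signalling that rises and falls with the day stays open. HOX genes of groups 1 to 4 outside the RA list were also higher on odd days (8 of 10, camera p = 2.3e-15, and 7.8e-06 with an estimated correlation), but their list had already been seen to alternate.

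What differed between odd and even days stays open. The labels give no batch or time of day. Odd and even days handled as separate batches, or feeding or collection times, changed after day 8 or not, cannot be separated from RA signalling itself. The alternation reached beyond RA genes, with 11 of 15 cholesterol genes (camera adjusted p = 1.2e-09, and 0.034 with an estimated correlation) and 19 of 24 cell cycle genes (9.4e-15, lost at 0.088) lower on odd days. Over days 10 to 15 these were 8 of 15 and 16 of 24 (0.0071 and 0.049 with an estimated correlation). Over days 11 to 15, 1 of 15 and 10 of 24 were lower, and both calls were lost with an estimated correlation (0.065 and 0.055), while that of the RA list was kept (5 of 10 higher, 0.00041). Comparisons with day 15 carry this difference, as day 8 is even.

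The step from day 9 to day 10 held 3161 genes higher and 2740 lower. The alternation of odd and even days does not account for most of the 2-fold changes. Genes chosen against 1 library of day 9 were still called in the same direction on day 11 against the other 2 libraries in 70.5% to 73.5% of cases, against 3.6% to 6.5% of genes with little change (p of at least 0.5) on day 10. A trend with GC content or gene length is argued against as the whole cause, since it held 0.4% of the variance and came to at most 0.21 in any gene on the log2 scale, and 96% of the 1003 genes kept a 2-fold change after its removal. A lower share of neurons stays open for the pan-neuronal genes that fell. Of 18 such genes 13 were lower (camera adjusted p = 2.5e-05, lost at 0.36 with an estimated correlation), but NEFL (1516 ± 41 and 1441 ± 195 CPM), MAP2 (669 ± 36 and 668 ± 12 CPM) and RBFOX3 (5.3 ± 0.68 and 5.64 ± 0.99 CPM) did not pass. NEFM did not pass either, but its mean was lower on day 10 (2029.9 ± 97 and 1494 ± 349 CPM). PRPH, of the motor neuron list, rose from 10 ± 1.5 to 19.3 ± 2.1 CPM. If a lower share of neurons raised the 772 genes at least 2-fold, the neural progenitor genes would have to rise about 2-fold too. This holds only if the remaining cells kept their level of them. Their median log2 change was -0.11 with an SD of 0.61 over 12 members (4 higher, 6 lower), and the highest was 0.24 ± 0.08. These values argue against a lower share of neurons only on that condition, as 7 of the 12 fell and 2 rose from day 8 to day 15. A rise of other cell types stays open, as 7 of 10 floor plate and p3 genes and 7 of 14 gliogenic genes were higher (camera adjusted p = 0.00025 and 0.054, and 0.2 and 0.1 with an estimated correlation). A change of handling at that day was not tested, as the labels record none.

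Other splits of the libraries were compared with the real days. For each stage, the 6 libraries make 10 splits into 3 and 3, and 1 split, the real one, gave as many genes, with 0 genes in the highest other split. The real splits, fitted alone, gave 5729 genes higher and 6012 lower on day 1, 4318 and 4238 on day 4, 5062 and 4556 on day 8, and 4626 and 4605 on day 15. The 10 splits are too few for a share under 0.05. For all days, 1 of 100 splits, the real one, gave as many as 17930 genes and the highest other gave 9297, so chance assignment of libraries to days is excluded at 0.05.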
